A study of Oryza sativa with 21 samples.

How the data were processed

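The series measured rice (Oryza sativa) of the cultivar ZH11 and of DRW1 overexpression lines made in it. RNA-seq was done on grains collected 3 days after pollination from paddy-grown plants, with 3 libraries each of ZH11, line OE1 and line OE2. RNA m5C IP-seq, in which RNA fragments carrying 5-methylcytosine are pulled down with an antibody and sequenced beside an input sample, was done on seedlings 3 weeks after germination from chamber-grown plants, with 3 immunoprecipitated and 3 input libraries each of ZH11 and OE1. Samples were grouped from their titles. The labels do not say whether the replicates are separate plants, so p-values measure only the spread between these samples, which may be technical.

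The grain table holds counts of reads per gene as the authors deposited them, whole numbers that sum to between 33237306 and 38117144 per library. The submitters' processing notes name HISAT2, featureCounts, DESeq and BWA without versions or roles, and the genome build, annotation and strand setting are not given in the sources used here. Reads of a gene and of an antisense partner, and reads shared by near-identical members of multigene families, therefore could not be told apart. Among counts of 1 to 20, 64.9% to 68.1% were even in each library, against 49.4% to 50.6% of counts above 100. Such an excess arises where each mate of a pair is counted separately, and the number of independent fragments is then smaller than the count. Each seedling peak list pairs an immunoprecipitated library with an input, per the labels. The lists hold, per peak, a score, an enrichment ratio and −log10 values of p and q, all as the authors deposited them. The score equals 10 times the −log10 p without its decimals and was not used here. The peak caller and the genome build of the peaks are not given in the sources used here. The smallest −log10 p in a list lay between 1.30 and 1.31, so the lists include peaks whose q is above 0.05.

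The table names 39217 genes by rice locus identifiers. The reference held pairs other identifiers with symbols, so 0 of the table's identifiers matched it directly and gene positions are not given. A gene symbol is printed only where the identifier and symbol were paired beforehand from general knowledge and the reference carries that symbol on the chromosome that the identifier states, in the same order along it. Of 205 such pairs in all gene lists, 116 passed, 84 had a symbol not found in the reference and are counted within their lists without being named, and 5 were contradicted and dropped. DRW1 did not match any symbol in the reference, so the overexpressed gene itself is not analysed here.

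Grain counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with edgeR's default expression filter on the groups, which left 24765 genes to test and 14452 untested. Libraries were scaled with TMM factors, and CPM values below use them. The quasi-likelihood test of edgeR, with robust dispersion estimates and group as its only factor, was fitted on all 9 libraries. It gave the contrasts of the mean of both lines against ZH11, of each line against ZH11 and of OE1 against OE2. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. In simulated counts for the averaged contrast, over 23426 genes, the test found 77.6% of 67 genes changed 1.5-fold, 94% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and called 0.00861% of unchanged genes. Only these few genes were changed, balanced up and down, with independent counts. In the grain data 73.6% of tested genes were called in that contrast, so the simulated rates need not hold there.

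Gene lists were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, for lists with at least 4 tested genes. The designs, tests, alternatives, naming rule and 5 gene lists were fixed before the data were examined: starch synthesis, seed storage proteins, grain size regulators, sugar import and cleavage, and endosperm transcription factors with imprinted genes. Further lists, RNA m5C methyltransferases among them, had been fixed as keywords on gene descriptions, which the reference does not carry, and were not run. In their place 9 lists were written before any test, after the identifiers had been read: cell cycle, photosynthesis, embryo and aleurone, heat shock, defence and phytoalexins, cytokinin, gibberellin, floral organ identity, and early endosperm MADS and Polycomb genes. A list of phenylpropanoid and secondary wall genes was chosen after values had been seen. The naming rule took the up to 4 members of smallest adjusted p from each list, the 10 genes of largest fold in each direction of the averaged contrast among genes called in both lines with a CPM of at least 5, and the 5 of largest fold each way between the lines. For unnamed identifiers, only the first 2 in each direction are printed. A fold against a group at 0 in all its libraries is a lower bound, computed with a floor of 3 counts per library, which covers counting error only.

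Peaks of the 6 lists were merged into regions with bedtools 2.31.1, and a region was present in a list when at least 1 bp of a peak overlapped it. Starts are counted from 1. Numbers of peaks were compared by an exact two-sided permutation test, whose smallest possible p with 3 lists against 3 is 0.1. Because the build is not known, regions were not assigned to genes, and the planned comparison of regions with grain calls was not run. The background level of each list was recovered as the Poisson mean whose upper tails give the most frequent deposited p-values. A level within 0.002 of 1 was not searched. On simulated data with 3 known background levels the largest error was 2.2e-06, and 100 of 100 simulated regions fell in their class. Those regions lay far apart and were present or absent without error. Their recovery therefore checks the computation and not how reliable the classes are in these lists. Correlations over chromosomes used permutation tests with 100000 resamples (Python 3.11.15, scipy 1.17.1).

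Alternatives were median-ratio (RLE) size factors, library totals only, DESeq2 1.42.0, no filter on low counts, a CPM of at least 1 in at least 3 libraries, only the groups compared, the replicate number as a block, a 2-fold minimum, leaving out each library or list in turn, an estimated inter-gene correlation, a −log10 q of at least 5, lists of equal length, a covered share of at least 0.5 of a region, and presence in at least 2 of 3 lists. A −log10 q of at least 1.3, all settings of the 9 added lists and the camera tests in each line alone, with either correlation, were chosen after seeing the data.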

Results

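Grains at 3 days after pollination were profiled by RNA-seq in wild-type rice ZH11 and in the DRW1 overexpression lines OE1 and OE2, and RNA m5C was mapped in ZH11 and OE1 seedlings, to ask how DRW1 overexpression alters transcript levels and m5C. The 9 grain libraries held 33237306 to 38117144 counts each. Log2 CPM values correlated across genes at 0.983 to 0.989 between libraries of a group, at 0.910 to 0.913 between OE1 and OE2, at 0.868 to 0.871 between ZH11 and OE1, and at 0.804 to 0.807 between ZH11 and OE2. Genes are not independent replicates in these correlations. The chi-square per degree of freedom was 3.99 to 6.17 within groups and at least 223 between groups. No pair of libraries agreed within counting noise, so none were summed, but repeat libraries of one RNA can differ by more than that too, and whether the 3 libraries of a group are separate plants is not known.

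In the mean of both lines against ZH11, genes of starch synthesis moved in opposite directions. Transcripts of starch synthase SSI, which extends short amylopectin chains, fell from 195 ± 7.12 CPM (SD, n = 3) in ZH11 to 137 ± 4.73 in OE1 and 56.4 ± 3.81 in OE2, a log2 change of −1.15 (SE 0.04, adjusted p = 2.66e-23). SSIIb fell as well (log2 change −0.88, SE 0.07, adjusted p = 5.24e-14). The granule-bound starch synthase gene GBSSI/Wx, which makes amylose, rose from 1.44 ± 0.114 CPM to 24.5 ± 1.69 in OE1 and 3.65 ± 0.854 in OE2 (log2 change 2.72, SE 0.15, adjusted p = 1.42e-17). SSIIa, which lengthens amylopectin chains in the endosperm, rose from 13.3 ± 2.00 CPM to 47.2 ± 3.86 and 27.8 ± 0.717. Of 24 starch genes tested, 6 rose, 15 fell and 3 did not pass, and the 21 changed genes were also 21 when adjusted over the list alone. With library totals as the scaling 3 rose and 21 fell (median −0.88). Of all tested genes 73.6% were called in the averaged contrast. A count of changed members, adjusted either way, therefore does not by itself set this or a later list apart. The starch list lay lower than other genes (median log2 change −0.34, camera adjusted p = 0.0336 over 5 lists), but not with an estimated correlation (adjusted p = 0.36) or with the replicate number as a block (adjusted p = 0.0506).

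Glutelin genes encode the main storage proteins of the rice endosperm. Of the 4 that could be tested, 3 stood at 0.240 CPM or less in ZH11 grains of this age, and all were higher in the mean of both lines. GluA3 stood at 0.240 ± 0.0796 CPM in ZH11, 0.413 ± 0.288 in OE1 and 2.20 ± 0.249 in OE2 (log2 change 1.99, SE 0.48, adjusted p = 0.000434). In OE1 alone GluA3 did not pass (log2 change 0.79, adjusted p = 0.212). GluB5 rose by a log2 change of 2.78 (SE 0.87, adjusted p = 0.0049) and GluB2 by 2.08 (SE 0.67, adjusted p = 0.00588), each from under 0.2 CPM. With a library left out, GluB5 went down to 2.14 and GluB2 ran from 1.46 to 2.82. GluB2 no longer passed without OE1 replicate 3 (adjusted p = 0.0532). GluA2, the most abundant of these in ZH11 at 3.79 ± 0.391 CPM, rose by 0.52 (SE 0.16, adjusted p = 0.00404), a change that became −0.02 with library totals as the scaling. The 4 storage protein genes with enough counts all rose on average, 4 also when adjusted over the list alone, while 2 passed in OE1 and 3 in OE2 taken by themselves. As a list they did not pass the camera test (median log2 change 2.04, adjusted p = 0.262).

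Among regulators of grain size, GW8/SPL16, a transcription factor gene that promotes grain width, fell from 8.60 ± 1.15 CPM to 2.79 ± 0.137 in OE1 and 0.348 ± 0.141 in OE2 (log2 change −3.12, SE 0.18, adjusted p = 8.2e-17). BG1, which promotes grain size through auxin transport, fell by a log2 change of −1.96 (SE 0.15, adjusted p = 5.62e-14). The brassinosteroid receptor gene BRI1/D61 fell on average (log2 change −0.65, SE 0.04, adjusted p = 6.69e-18), with 193 ± 4.20 CPM in ZH11, 236 ± 2.89 in OE1 and 63.8 ± 1.41 in OE2. D2, a brassinosteroid synthesis gene, stood at 10.6 ± 0.912 CPM in ZH11, 10.3 ± 0.812 in OE1 and 62.1 ± 3.89 in OE2, and rose on average by 1.26 (SE 0.08, adjusted p = 3.03e-16). Of 23 members tested 6 rose, 14 fell and 3 did not pass, and 20 changed when adjusted over the list alone, as over all genes. The list did not pass the camera test (median log2 change −0.54, adjusted p = 0.154), and with library totals 2 members rose and 19 fell (median −1.07). In camera tests by line, added after seeing the data, the list passed in OE2 and not in OE1. In OE2 6 rose and 16 fell (median −1.15, camera adjusted p = 0.0334, 0.205 with an estimated correlation). In OE1 8 rose and 11 fell (median −0.04, camera adjusted p = 0.926).

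The sugar transporter genes SWEET4 and SUT4 rose while SWEET14 and the invertase gene CIN2/GIF1 of the developing grain fell. SWEET4, a hexose transporter of the seed-filling path, rose from 114 ± 4.80 CPM to 373 ± 14.3 in OE1 and 621 ± 14.8 in OE2 (log2 change 2.07, SE 0.04, adjusted p = 1.13e-31). The sucrose transporter gene SUT4 rose from 42.1 ± 1.52 to 144 ± 5.54 and 123 ± 2.78 CPM. The invertase gene CIN2/GIF1, known for its role in grain filling, fell from 321 ± 9.18 to 157 ± 6.45 and 127 ± 2.97 CPM (log2 change −1.19, SE 0.04, adjusted p = 1.2e-25). SWEET14, picked after its values were seen as a transporter that went the other way, changed by −2.16 (adjusted p = 6.85e-17). CIN1, another invertase gene, rose by log2 changes of 0.31 in OE1 (adjusted p = 0.000431) and 3.80 in OE2 (adjusted p = 5.3e-32). Of 15 members 9 rose, 4 fell and 2 did not pass, and 13 changed when adjusted over the list alone, as over all genes. The list did not pass the camera test (median log2 change 0.18, or 0.17 without the member at 0 in all ZH11 libraries; adjusted p = 0.235), and with library totals its median was −0.35 with 7 members higher and 8 lower.

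The endosperm transcription factor gene NF-YB1, which acts in aleurone sugar loading, rose from 0.389 ± 0.0908 CPM to 2.13 ± 0.504 in OE1 and 1.98 ± 0.504 in OE2 (log2 change 2.39, SE 0.35, adjusted p = 2.53e-07). MADS29, needed for degradation of maternal tissue in the young seed, was at 122 ± 1.68 CPM in ZH11, 101 ± 5.59 in OE1 and 131 ± 10.4 in OE2 and did not pass (log2 change −0.09, SE 0.04, adjusted p = 0.0716). It passed without OE1 replicate 3 (−0.11, adjusted p = 0.0279), without OE2 replicate 1 (−0.12, adjusted p = 0.0102), without a filter on low counts (−0.10, adjusted p = 0.0344) and with library totals (−0.62). Of 6 endosperm regulators and imprinted genes tested, 3 rose, 1 fell and 2 did not pass. The 4 changed genes were also 4 when adjusted over the list alone, and the list did not pass the camera test (median log2 change 0.24, adjusted p = 0.338). With library totals 2 rose and 3 fell, and the median turned to −0.30.

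Most markers of green tissue, and most but not all floral organ genes, were lower in the mean of both lines. The chlorophyll-binding protein genes CAB2R and CAB1R, expressed in green tissue, fell by log2 changes of −1.26 (SE 0.04) and −1.13 (SE 0.05). Of 15 photosynthesis genes 14 fell and 1 rose, with a median log2 change of −0.94 (camera adjusted p = 4.48e-05 over the 9 added lists, 0.104 with an estimated correlation). In this list only CAB2R and CAB1R have symbols found in the reference, so the other members rest on pairs that could not be checked. The floral organ identity genes MADS58 and MADS3, which specify carpels and stamens, fell from 219 ± 3.24 to 98.0 ± 4.05 and 111 ± 3.37 CPM, and from 185 ± 2.91 to 87.4 ± 2.33 and 79.4 ± 6.51 CPM. Of 14 such genes 10 fell, 3 rose and 1 did not pass (camera adjusted p = 0.0266, 0.185 with an estimated correlation). Taken by line, 10 fell in OE1 (camera adjusted p = 0.0381) and 7 in OE2 (camera adjusted p = 0.143), with 3 higher in each, and in OE1 too the call was lost with an estimated correlation (adjusted p = 0.201). With library totals 13 were lower and 0 higher. In the mean of both lines 7 of 9 cell cycle genes fell and 2 did not pass, among the former PCNA, the sliding clamp of DNA replication, from 99.2 ± 3.18 to 56.7 ± 1.62 and 35.8 ± 1.80 CPM (list median −0.53, camera adjusted p = 0.00528, 0.0974 with an estimated correlation). In OE1 6 of these genes fell and 2 rose (camera adjusted p = 0.143), and in OE2 all 9 fell (camera adjusted p = 0.000458, 0.0613 with an estimated correlation). In the embryo and aleurone list, VP1, an abscisic acid response regulator, rose from 0.801 ± 0.232 to 3.70 ± 0.368 and 2.33 ± 1.06 CPM, and LEA3 rose by a log2 change of 1.09 (SE 0.09, adjusted p = 5.1e-13). OSH1, an embryo and meristem homeobox gene, had a log2 change of −0.43 (SE 0.12, adjusted p = 0.00136) on average, from −1.03 in OE1 (adjusted p = 8.82e-08) and 0.17 in OE2, where it did not pass (adjusted p = 0.24). Of these 8 genes 4 rose, 1 fell and 3 did not pass (camera adjusted p = 0.248). The embryo oil body gene OLE18 did not pass (log2 change 0.77, SE 0.46, adjusted p = 0.133) unless ZH11 replicate 1 was left out (1.72, adjusted p = 0.00727).

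Across the transcriptome, 9173 of 24765 tested genes were higher and 9062 lower in the mean of both lines than in ZH11, and 4872 and 3163 of them by at least 2-fold. All 6 OE libraries lay above all 3 ZH11 libraries for 6445 genes (26%) and below them for 6283 (25.4%). Freely exchangeable libraries would give 1.19% each way. Libraries of a group resemble each other, however, so that share does not measure chance here. Among the genes of largest fitted change, several were at 0 in a whole group. LOC_Os03g61500 had 0 counts in all ZH11 libraries, 6.26 ± 1.24 CPM in OE1 and 136 ± 2.12 in OE2, at least 96.6-fold and 2100-fold higher, and LOC_Os06g05510 was at least 160-fold and 1170-fold higher. Of the 10 top genes in this direction 8 were at 0 in all ZH11 libraries, and of the 10 in the other direction 3 were at 0 in OE2 and 1 in OE1. LOC_Os12g17570 fell from 13.2 ± 1.21 CPM to 0.240 ± 0.0286 in OE1 (55.2-fold lower) and to 0 counts in OE2 (at least 140-fold lower), and LOC_Os03g30470 was 25.8-fold and at least 109-fold lower. The balance of calls depended on scaling: TMM factors were 1.28 to 1.29 in ZH11 and 0.863 to 0.907 in the OE lines, and library totals alone moved the median of all genes by −0.535, to 5518 higher and 15103 lower genes (26.8% higher, against 50.3% with TMM). Of the 100 most abundant genes' counts, the share was 10.1% to 10.3% of the total in ZH11, 12.6% to 13.1% in OE1 and 13.4% to 13.7% in OE2.

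**Figure D1:**
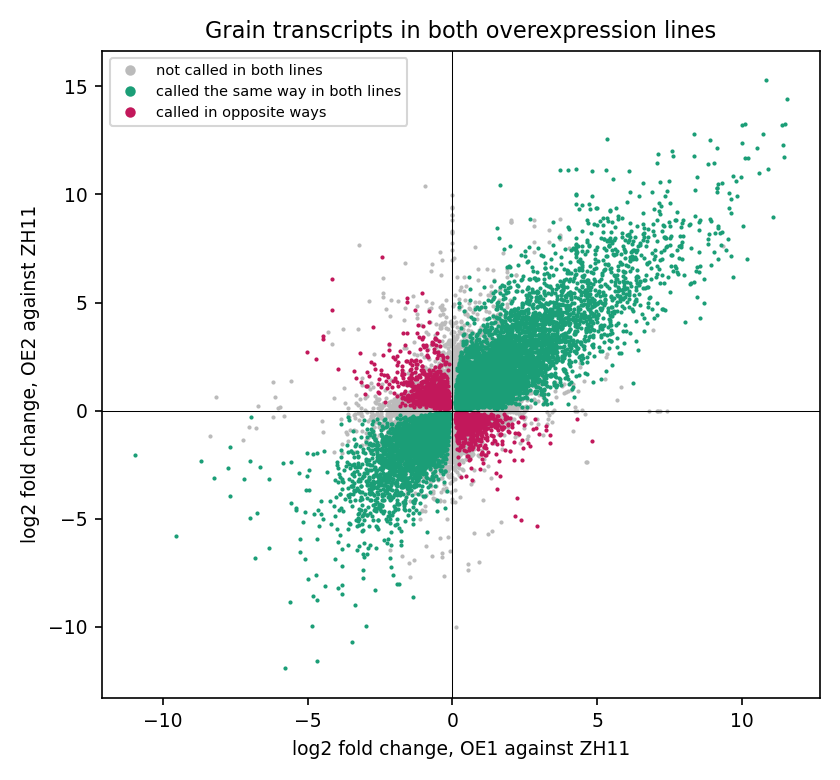
Log2 fold changes against ZH11 in line OE1 (horizontal axis) and line OE2 (vertical axis), one point for each of the 24765 tested genes, coloured by whether both lines were called in the same direction, in opposite directions (1833 genes) or not both. Most called genes lie in the quadrants of shared direction, and both axes share the ZH11 libraries.

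Taken by line, OE1 had 8399 genes higher and 8375 lower than ZH11, and OE2 had 9506 higher and 8912 lower. The lines shared 6391 higher and 5686 lower genes, against 3224 and 3014 for independent lists of those lengths. GBSSI/Wx, SSIIa, SWEET4, SUT4 and NF-YB1 were higher, and SSI, GW8/SPL16, BG1, CIN2/GIF1, PCNA, CAB2R and MADS58 lower, in each line. Because both comparisons use the same ZH11 libraries, unchanged groups were simulated against them 20 times. The overlap was 0 genes, the correlation of fold changes 0.474, their covariance 0.0249 and the same-sign share 66%. The simulated groups held only the spread between libraries of a group, so an overlap near 0 was fixed in advance. They do not show what sharing the controls adds where groups differ. The observed correlation across genes was 0.769, the covariance 2.38 and the same-sign share 75.3%. With 3 control libraries the controls could not be split into sets of at least 2 each, and part of the excess over independent lists may come from sharing them.

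The lines also differed from each other. Between OE1 and OE2, 16148 of 24765 genes differed (8116 higher and 8032 lower in OE1), 5953 of them by at least 2-fold, and 818 genes were higher in OE1 and lower in OE2 than ZH11 while 1015 did the opposite. Starch genes illustrate this: in OE1 9 rose and 9 fell (median log2 change −0.04, camera adjusted p = 0.926), and in OE2 4 rose and 19 fell (median −0.89, camera adjusted p = 0.000148, 0.205 with an estimated correlation). These camera tests by line were added after seeing the data, and the difference between their results was not tested. GBSSI/Wx was higher in OE1 than OE2 by a log2 difference of 2.75 (SE 0.15, adjusted p = 9.71e-18), and BRI1/D61 by 1.89 (SE 0.04, adjusted p = 5.15e-28). CIN1 was lower in OE1 than OE2 by −3.49 (SE 0.07, adjusted p = 7.47e-30) and D2 by −2.59 (SE 0.09, adjusted p = 2.03e-23). The 5 genes of largest fold toward OE1 had log2 differences of 4.72 to 6.24, and the 5 toward OE2 had 5.25 to 244 CPM in OE2 and 0 to 0.544 in OE1.

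**Figure D2:**
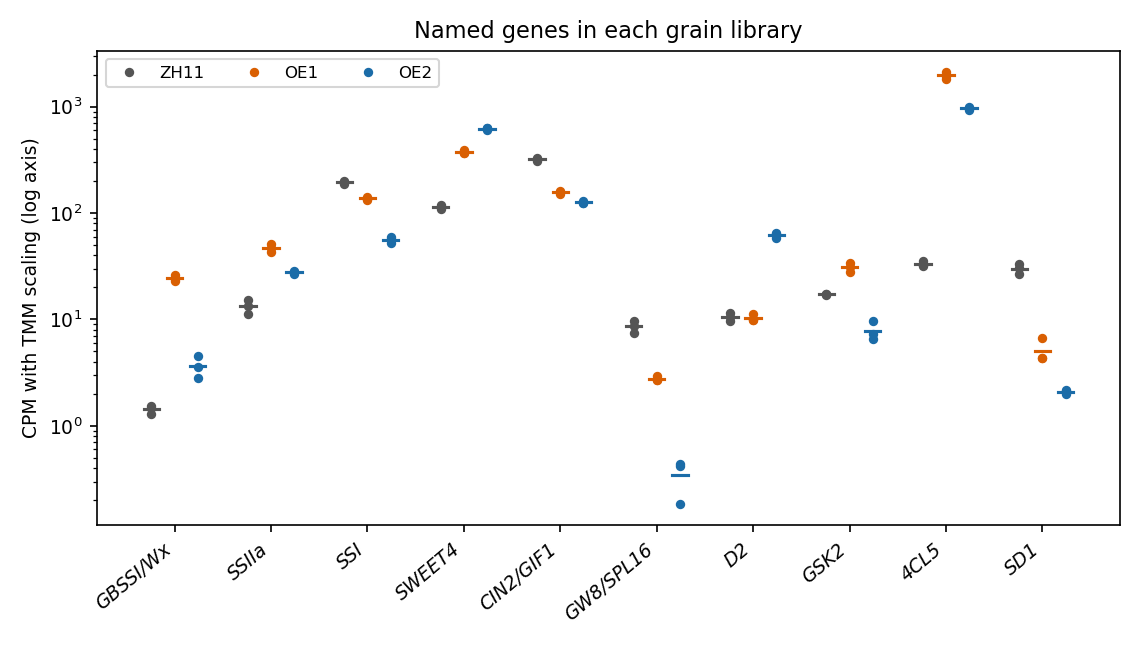
CPM with TMM scaling (log axis) of 10 named genes in each of the 9 grain libraries, with a point per library and a bar at the mean of the 3 libraries of ZH11, OE1 and OE2. GBSSI/Wx, SSIIa, SWEET4 and 4CL5 lie higher in both lines than in ZH11, SSI, CIN2/GIF1, GW8/SPL16 and SD1 lie lower in both, and GSK2 lies above ZH11 in OE1 and below it in OE2.

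In seedlings, the OE1 lists held more m5C peaks than the ZH11 lists: 92024 ± 2161 against 73680 ± 5660 (SD, n = 3 lists each), a ratio of 1.25 (exact two-sided permutation p = 0.1, the smallest that 3 lists against 3 can give). The covered length was 38.9 ± 3.13 Mb in OE1 and 24.1 ± 5.54 Mb in ZH11. Peaks with q below 0.05 made up 75.3% to 83.6% of the OE1 lists and 59.2% to 68.9% of the ZH11 lists. With a −log10 q of at least 5, the ratio of mean numbers was 3.73. The read depth of these libraries is not given by the lists. Whether the 3 lists of a genotype were called against separate inputs is not known. Covered bases overlapped with a Jaccard index of 0.61 to 0.634 between OE1 lists, 0.362 to 0.549 between ZH11 lists and 0.331 to 0.587 between the genotypes. ZH11 replicate 2, which covered 18.4 Mb, lay lowest, at 0.331 to 0.382 with every other list. ZH11 replicate 1 overlapped the OE1 lists at 0.552 to 0.587, above its 0.382 and 0.549 with the other ZH11 lists. By this index the ZH11 lists did not group together.

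Merging all lists gave 111849 regions, of which 35083 (31.4%) were present in all 6 lists, 3815 in all OE1 lists and no ZH11 list, and 217 in all ZH11 lists and no OE1 list. With lists shortened to the 67984 peaks of smallest q, the OE1-only and ZH11-only counts were 1497 and 800. The OE1-only count was 5686 to 7126 and the ZH11-only count 353 to 625 when any list was left out, since fewer lists then had to agree. Enrichment values are the authors' own and describe peaks within a list, and the build behind these coordinates is not given in the sources used here. The strongest OE1-only regions were on Contig00096 at 37151 to 37399 (mean enrichment 9.01 ± 2.38, SD over 3 lists), on Contig00087 at 71855 to 72006 (8.02 ± 0.607), on chromosome 11 at 14569285 to 14569517 (6.16 ± 1.07) and on chromosome 5 at 9852814 to 9853073 (5.74 ± 1.33). The strongest ZH11-only regions were on chromosome 6 at 26831678 to 26831963 (5.46 ± 1.63), on chromosome 12 at 11572546 to 11572902 (5.30 ± 0.311) and on chromosome 1 at 3223315 to 3223483 (4.91 ± 0.277). Among regions in all 6 lists the highest mean enrichment, 13.7 ± 1.57, was on chromosome 7 at 12079721 to 12080630. Genes or transcript parts under these regions are not analysed here.

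**Figure D3:**
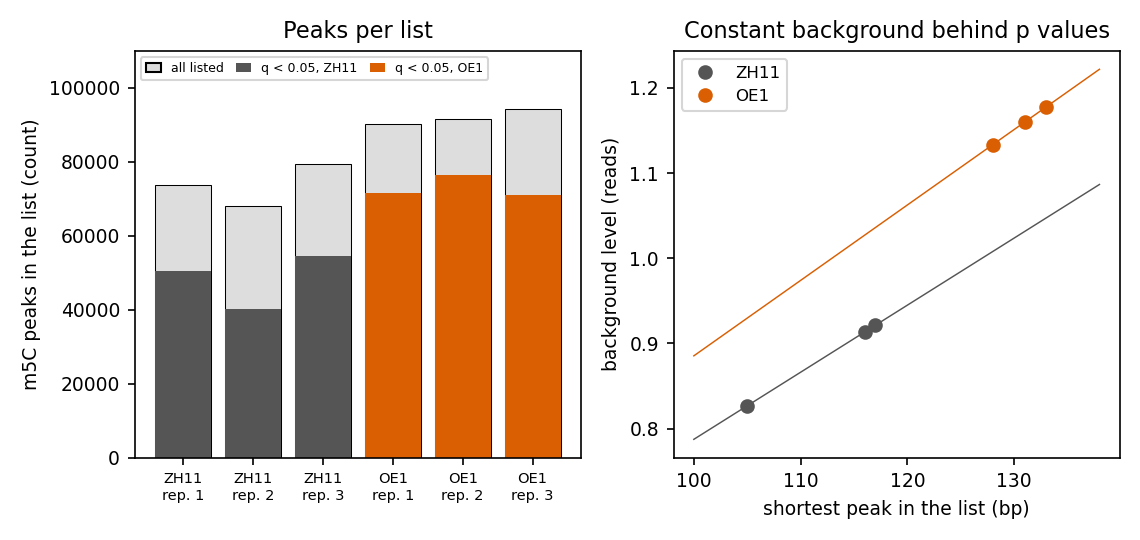
Left, number of m5C peaks in each of the 6 seedling lists, with grey bars for all listed peaks and coloured bars for those with q below 0.05. Right, the constant background level recovered from the deposited p-values against the length of the shortest peak (bp), a point per list, with a line through the origin for each genotype. The OE1 lists hold 90132 to 94379 peaks and the ZH11 lists 67984 to 79303, and background levels are 1.13 to 1.18 in OE1 and 0.827 to 0.921 in ZH11.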

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

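The tests of tissue share, of background level, of a common input total and of list agreement at equal length below were chosen after the results had been seen, and the others before. The effects of the lines differed by their own test for 16148 genes, and 1833 genes were called in opposite directions against ZH11. Among members of the lists fixed before the data were examined, opposite effects of some size were seen in GSK2, a kinase gene of brassinosteroid signalling, with log2 changes of 0.85 in OE1 and −1.15 in OE2 (difference 1.99, edgeR adjusted p = 4.77e-17). The sucrose synthase gene SUS3 had 0.94 in OE1 and −0.57 in OE2 (difference 1.52, adjusted p = 6.04e-25). Of 72 tested members 13 were called in opposite directions, 4 of them by a log2 change of at least 0.5 in each line, and 2 of those 4, with a difference of up to 3.37 in size, have symbols not found in the reference and are not named. Splits of OE1 against OE2 were too few for a share under 0.05: the real grouping, fitted on those 6 libraries alone, gave 15634 genes, was 1 of 10 splits, and the highest other gave 0. The same holds for OE1 against ZH11 (16772 genes, 1 of 10, highest other 0) and OE2 against ZH11 (18533, 1 of 10, highest other 0).

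The first pattern is that most tested genes differed between the OE lines and ZH11, 18235 in the averaged contrast. The lowest number of calls under RLE factors and library totals was 18205, so the number did not depend on the choice among these scalings, though their direction did. RLE factors lay close to the TMM factors. Library totals moved the median log2 change of all genes from −0.02 to −0.555, which adds calls more readily than it removes them. Scaling as the cause of the number is therefore not decided by these 2 settings. A smaller share of green and floral tissue alone, with other tissues in fixed proportions, would raise transcripts absent from it by a common factor. Of the genes higher in both lines, 17.9% exceeded 4 times their median fold of 2.74. This argues against that simple case only, and shifts among several tissues stay open. For the genes that were lower, a smaller share of green and floral tissue cannot be told apart from an effect in other cells. There 0 floral organ markers were 2-fold higher in both lines, while 3 rose by less. Repeat libraries of a single RNA per group could also not be excluded with a biological coefficient of variation of 0.0773. An effect of DRW1 or of grain age stays open, untested.

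Whether chance in how libraries fell into groups gave that number cannot be decided by splits of the 9 libraries. The drawn splits other than the real one mix libraries of different groups, which widens the spread within a group. Of 100 drawn splits (840 possible) 1, the real one, gave as many genes, and the highest other gave 11319. The same was so for genes higher in both lines (6391, 1 of 100, highest other 4751) and lower in both (5686, 1 of 100, highest other 3279), but whole groups exchanged, which the draws did not hold, gave 14980 calls with OE1 and 17837 with OE2 as the control, and 5764 genes lower in both with OE2, more than the real 5686. Genes higher in both were 3003 and 5195 in those exchanges, fewer than the real 6391. The camera test on the fixed lists passed for 1 list, and 60 of 100 splits passed at least as many (highest other 3). The number of lists passed thus does not set the real grouping apart from the drawn ones. Drawn groupings can still hold part of the group differences, so they do not show what random assignment alone would give.

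The second pattern is the larger number of m5C peaks in OE1 lists. At equal list lengths OE1-only regions outnumbered ZH11-only regions by a ratio of 1.87, but longer lists alone cannot be told apart from other causes by it, since OE1 lists also overlapped more with each other there (Jaccard index 0.591 to 0.61, against 0.345 to 0.52 in ZH11), which favours OE1 in a count of regions present in all 3 lists. A higher background level in the OE1 lists may contribute, as deeper libraries give both a higher level and more power. The share of peaks whose p-value came from the constant level was 72% to 73.7% in OE1 lists and 47.4% to 47.8% in ZH11 lists. The genotypes thus differed in how peaks were scored, not only in their number. Whether the excess of peaks lies among those scored at the constant level was not tested. The lowest OE1 level, 1.13 reads, lay above the highest ZH11 level, 0.921. The mean level was 1.3 times that of ZH11, but the shortest peak was also 1.16 times as long. Divided by that length, the level was 1.12 times as high, so depth need not account for the whole gap. The level per length of the shortest peak was 7874 per Mb in all 3 ZH11 lists and 8854 in all 3 OE1 lists, a gap of 12.4%. One input total behind the 3 lists of a genotype would give this. The lists of a genotype would then not be independent, and the level could not reflect the depth of each library. Their SDs, the permutation p and the counts of regions in all 3 lists may then reflect one input against another. A difference in m5C between the genotypes stays open. Splits of the lists were too few for a share under 0.05: the real grouping gave 3815 OE1-only regions (1 of 10 splits, highest other 985), and for the 217 ZH11-only regions all 10 of 10 gave as many (highest other 985).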

How the results depend on the processing

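Of the counts of called genes, all 9 stayed within 1.5 times under RLE factors, DESeq2, both alternative filters, the replicate block and leaving out any library; 9 settings of the last kind gave 8818 to 9198 higher and 8423 to 9140 lower genes in the averaged contrast, 8092 to 8515 and 7737 to 8499 in OE1, 9262 to 9705 and 8448 to 9067 in OE2, 15353 to 16065 between the lines, and 6170 to 6334 and 5156 to 5581 shared. Fits of only the groups compared gave 15634 genes between the lines. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at −0.0161 to 0.035, and 0 libraries correlated best with their own number in both other groups. With the number as a block 9106 genes were higher and 8995 lower in the averaged contrast, and among named genes and lists the only call it changed was that of the starch list, leaving 0 fixed lists past the camera test. An estimated correlation left 0 of the fixed and 0 of the 9 added lists, of which 4 passed with the preset value, and 0 fixed lists in OE2 alone against 2 (starch and grain size) with that value; each left-out library kept 1 fixed list.

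Library totals as the scaling gave 5518 higher and 15103 lower genes in the averaged contrast, 5115 and 14666 in OE1, 6050 and 14233 in OE2, and 3833 and 11899 shared, by the construction of a shifted median; 1680 genes called higher became lower. GluA2 turned to −0.02 and SUS3, 0.18 with TMM, to −0.35. A 2-fold minimum, which removes small changes by construction, left 4872 and 3163, 4473 and 2967, 5497 and 3957, 5953 between the lines, and 3375 and 1685 shared. Of 59 named genes followed, 6 changed a call in another setting than the 2-fold minimum, which ended 11; GluB5 and GluB2 fell below the filter at a CPM of 1. GSK2, not called in the averaged contrast, passed with library totals and without OE2 replicate 1 (−0.24, adjusted p = 0.013).

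Peak results moved more. A −log10 q of at least 5 gave a ratio of 3.73, with 2396 OE1-only, 15 ZH11-only and 425 common regions, and the looser q of 0.05, added after seeing the data, gave 18731 common regions. Equal lengths gave 1497 OE1-only and 800 ZH11-only regions; they fix the number of peaks, so no ratio exists. A covered share of 0.5 gave 7098 OE1-only and 8996 common regions, and 2 of 3 lists gave 11258, 1173 and 54611, by construction. Leaving out a list gave 5686 to 7126 OE1-only, 353 to 625 ZH11-only and 35975 to 44404 common regions, and ratios of 1.2 to 1.3. The cause of the other shifts was not tested. Not run were regions against grain calls, as the build is not known. Counts limit the storage protein genes, of which 7 had too few to test and 1 is absent from the table.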

Other observations

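The list of phenylpropanoid and secondary wall genes and all settings of the 9 added lists were chosen after the data had been seen, as was the test over chromosomes. Most listed genes of the phenylpropanoid pathway, which makes lignin precursors, rose in the mean of both lines. The 4-coumarate ligase gene 4CL5 rose from 33.4 ± 1.84 CPM (SD, n = 3) in ZH11 to 1963 ± 137 in OE1 and 967 ± 27.2 in OE2 (log2 change 5.37, SE 0.05, edgeR adjusted p = 9.21e-40). Its relatives 4CL3 and 4CL4 rose by 2.53 (SE 0.04) and 2.25 (SE 0.05), and the cinnamyl alcohol dehydrogenase gene CAD2 from 33.6 ± 3.28 CPM to 94.5 ± 5.38 and 462 ± 28.1. Of 25 genes tested 21 rose, 2 fell and 2 did not pass (median log2 change 1.96, with library totals 1.42 and 16 higher, 6 lower). By line 16 rose and 4 fell in OE1 (median 1.15), and 22 rose and 2 fell in OE2 (median 2.65). In the 2 lines 2 of these genes were called in opposite directions. As the list was picked for its values, its camera p is not given.

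Several genes for antimicrobial diterpenes, part of a mixed defence list and not tested as a set of their own, fell in the mean of both lines. CPS2 fell from 54.0 ± 2.84 to 12.5 ± 1.58 and 18.4 ± 0.510 CPM, CPS4 by a log2 change of −1.83 (SE 0.09), KSL7 by −1.54 (SE 0.10) and CYP99A2 by −1.87 (SE 0.15). Of 9 defence genes 8 fell and 1 rose (median −1.54, camera adjusted p = 0.00911, 0.0974 with an estimated correlation). By line 8 fell in OE1 and 6 in OE2, where the momilactone gene MAS did not pass (log2 change −0.20, adjusted p = 0.458). Of 6 heat shock genes 4 rose and 2 fell, without passing the camera test as a list (adjusted p = 0.229): HSP17.4 rose from 1.26 ± 0.152 to 13.6 ± 1.11 and 21.2 ± 2.56 CPM, HSP101 from 9.94 ± 0.702 to 56.0 ± 4.95 and 33.2 ± 4.29, and HSFA2C, a heat stress transcription factor gene, from 25.2 ± 0.252 to 104 ± 6.15 and 51.2 ± 3.91. HSFA2A rose from 0.0857 ± 0.111 to 7.21 ± 1.21 and 4.29 ± 1.48 CPM. Its log2 change of 5.96 rests on few ZH11 counts (0, 2 and 10 in the 3 libraries) and ran from 5.36 to 7.78 when a library was left out.

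Hormone genes split. SD1, a gibberellin synthesis gene, fell from 30.1 ± 3.28 to 5.11 ± 1.37 and 2.09 ± 0.110 CPM, and the DELLA repressor gene SLR1 from 239 ± 13.6 to 203 ± 12.7 and 98.3 ± 4.40, while the receptor gene GID1 rose by a log2 change of 1.01 (SE 0.05) and GAMYB by 1.00 (SE 0.05). Of 10 gibberellin genes 4 rose, 4 fell and 2 did not pass, with a median of 0.82, a mean of −0.62 and a camera direction of down (adjusted p = 0.905). The cytokinin oxidase genes CKX4 and CKX5 rose by 5.06 (SE 0.23) and 2.41 (SE 0.07) and the response regulator gene RR6 by 1.92 (SE 0.05), while CKX2, known for its effect on grain number, fell from 24.5 ± 0.853 to 2.03 ± 0.166 in OE1 and 17.9 ± 0.709 CPM in OE2. Of 9 cytokinin genes 5 rose and 4 fell (median 0.32, with library totals −0.21; camera adjusted p = 0.744). Among 5 early endosperm MADS and Polycomb genes 1 rose and 4 fell (camera adjusted p = 0.315), with EZ1, a histone methyltransferase gene, at −0.20 (SE 0.06). By line EZ1 did not pass in OE1 (edgeR adjusted p = 0.997) and fell by −0.40 in OE2 (adjusted p = 6.6e-06). Of the 5 genes, 2 rose and 2 fell in OE1, and 1 rose and 4 fell in OE2.

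Over 12 chromosomes, regions per Mb and loci per Mb had Spearman's rho = −0.559 (permutation p = 0.062, adjusted 0.124 over 4 relations) and Pearson's r = −0.803 (permutation p = 0.00235, adjusted 0.00506). Only the latter passed, and without chromosomes 1 and 3 r was −0.657 and rho −0.248. With regions present in all 6 lists rho was −0.308 (permutation p = 0.333) and r −0.486 (permutation p = 0.111). With tested genes in place of loci, all regions gave rho = −0.622 (permutation p = 0.0342, adjusted 0.124) and r = −0.8 (permutation p = 0.00253, adjusted 0.00506). Regions in all 6 lists then gave rho = −0.378 (permutation p = 0.227) and r = −0.43 (permutation p = 0.162). Signal from reads spread over the whole genome may be part of the lists, but the rank correlation leaves this undecided.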
